A study of Mus musculus with 36 samples.

How the data were processed

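RNA was measured by RNA-seq in 36 libraries of mouse embryos, 17 at the 2-cell and 19 at the 8-cell stage, in 6 groups taken from the labels of treatment and developmental stage. Each library was a pool of 4 to 5 embryos per the series' design text, and its cDNA was made with SMART-seq v4 per the labels' protocols. Replicate numbers were given in accession order, only name libraries and pair none. The values are estimated counts per gene symbol made by the authors with Bowtie2 and RSEM on mm10, per the submitters' processing notes. RSEM gives expected counts that need not be whole, and it divides reads that match several genes between them. The versions of these tools and the annotation are not given in the sources used here, and the deposited table held no normalized values. Per-sample columns that were not used numbered 0.

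From the deposited table the expected counts were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) with TMM normalization, the robust option, filterByExpr with a minimum count of 10 and a minimum total of 15, and Benjamini-Hochberg adjustment at 0.05. Comparisons within a stage were fitted on all libraries of that stage, and comparisons between stages and the interaction on all 36. The filter left 11799 genes at the 2-cell stage, 9850 at the 8-cell stage and 13158 over all libraries, with a biological coefficient of variation of 0.738, 0.609 and 0.703. The median 95% half-width of a log2 fold change was 1.22 for KRAB against Ctrl, 1.39 for Ctrl against NI and 1.42 for KRAB against NI at the 2-cell stage. At the 8-cell stage it was 1.01 for VP64 against Ctrl, 1.05 for Ctrl against NI and 1.01 for VP64 against NI. Between the stages it was 1.50 in NI and 1.30 in Ctrl, and it was 1.91 for the interaction. CPM are the rounded counts of a gene relative to its library's TMM-scaled total. Genes at 0 counts in a group are given as bounds against a floor of 3 counts over the group, and genes with 1 to 3 counts as ratios with a 95% interval. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.

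The 22 gene lists were fixed before the data were examined, as were the groups, the tests and most alternatives. Their members, and the number in the table, were 46 and 42 for genes of the 2-cell embryo and zygotic genome activation, 46 and 45 for ribosome biogenesis as the major activation of early cleavage, 78 and 78 for cytosolic ribosomal proteins, 72 and 70 for maternal oocyte transcripts, 31 and 31 for pluripotency and inner cell mass, and 32 and 32 for trophectoderm. They were 20 and 20 for primitive endoderm, 34 and 34 for compaction, polarity and junctions, 63 and 63 for DNA and histone methylation with chromatin assembly and remodelling, 42 and 41 for retrotransposon silencing and restriction, 44 and 44 for interferon and nucleic acid sensing, 38 and 38 for p53 targets and DNA damage, and 46 and 46 for integrated stress and heat shock. They were 48 and 48 for DNA replication, 41 and 41 for mitosis, 53 and 53 for nuclear genes of oxidative phosphorylation, 21 and 21 for glycolysis and glucose uptake, 30 and 29 for imprinted genes, 25 and 20 for X chromosome activity, 36 and 35 for cumulus and granulosa cells, 24 and 24 for sperm, and 15 and 0 for transcripts of the mitochondrial genome, which could therefore not be tested. Lists with at least 5 tested members were tested with camera (limma) at a preset correlation of 0.01, and again with an estimated correlation, with fry and with an exact permutation of each library's list mean. Of the 35 cumulus and granulosa genes in the table, 1 was also in another list, and of the 24 sperm genes 0 were.

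Named genes followed a rule. Among genes with adjusted p under 0.05, a mean of 10 CPM in at least 1 group and a symbol that is not a bare model name, the 10 largest rises and 10 largest falls were named, or the 5 smallest p-values where fewer than 5 genes qualified. From each list up to 4 members that passed were named, or the 2 most abundant where none passed. The examples printed are taken from these genes, the lists whose members are printed were chosen after the values were seen, and 4 further genes outside the rule are marked where they appear. Some genes that the rule named are not reported here. Coordinates come from GENCODE vM21 on GRCm38, the assembly that mm10 denotes. Symbols were matched for 98.65% of the 23845 genes, 22724 by symbol and 798 by synonym, while 44 lay at more than 1 locus and 323 were unmatched. Genes sharing 31-base words with near-identical copies have uncertain single values. An example is the Zscan4 family, where Zscan4c and Zscan4f shared 80.4% of the smaller of their word sets.

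The stage score is the mean log2(CPM + 1) of 200 rising genes minus that of 200 falling genes, chosen in NI, and its differences were tested by exact permutation over 1716 splits, two-sided. No replicate pair agreed within sampling noise, as the lowest chi-square per degree of freedom among 93 pairs within groups was 6.92. Total count, detected genes and the shares of Ccdc82 and of Rn45s, the ribosomal RNA precursor, did not differ between groups past the threshold (exact permutation tests, lowest adjusted p = 0.314). The labels give no sequencing batch or date.

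The alternatives were DESeq2 1.42.0, limma-voom with quality weights, the size factors of DESeq2, edgeR without the robust option, no filter, a filter at 10 CPM, a 2-fold threshold, only the groups compared, libraries under 33.3% of their stage's median total left out, the number of detected genes or the number in the sample titles (up to 48 or above) as a covariate, other axis sizes and pseudocounts for the score, and each library left out in turn. Chosen after the data were seen were the removal of a trend on transcript length, leaving out the 3 8-cell libraries with the fewest detected genes, leaving out Ccdc82, the exact permutation test of lists, a linear fit of the 2-cell list means with detected genes as covariate, the matching of genes on their ratio of 2-cell to 8-cell level, and a jackknife over libraries of the change of the ribosomal protein median under each correction. The edgeR and camera tests were checked on simulated data. For edgeR, 200 genes were changed independently of each other, drawn only from genes with a simulated mean of 10 CPM or more. Recovery of less abundant genes was not measured. With 50 genes per fold size, the share recovered at 2-fold, 4-fold, 8-fold and 16-fold was 2%, 32%, 82% and 94% for KRAB against Ctrl (11550 genes) and 4%, 56%, 100% and 100% for VP64 against Ctrl (9322 genes). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.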

Results

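The series profiled RNA of mouse embryos at the 2-cell and the 8-cell stage in 36 RNA-seq libraries, each made from a pool of 4 to 5 embryos with SMART-seq v4, a kit for amplifying cDNA from very small amounts of RNA. Its title concerns the switching on of LINE-1, a family of retrotransposons, in the fertilised egg and the openness of chromatin. The 2-cell libraries comprised 4 labelled NI, 7 labelled Ctrl and 6 labelled KRAB, and the 8-cell libraries comprised 6 NI, 6 Ctrl and 7 VP64. KRAB is the name of a known transcriptional repressor domain and VP64 that of a known activator domain, while the labels do not spell out NI or say what the Ctrl embryos received. The values were estimated counts for 23845 gene symbols, and LINE-1 elements themselves were not analysed here.

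Total counts per library at the 2-cell stage ranged from 1043740 to 10035066 in Ctrl, from 1296375 to 4336022 in KRAB and from 1376619 to 4962006 in NI. At the 8-cell stage they ranged from 1669772 to 7063742 in Ctrl, from 1103574 to 13583527 in NI and from 1462479 to 6699587 in VP64. Genes with at least 1 count numbered 14716 ± 1413 (SD, n = 7) in Ctrl, 14332 ± 950 (n = 6) in KRAB and 14340 ± 1179 (n = 4) in NI at the 2-cell stage. At the 8-cell stage they numbered 11951.5 ± 1516 (n = 6) in Ctrl, 12930.5 ± 1151 (n = 6) in NI and 13091 ± 1239 (n = 7) in VP64. A single gene, Ccdc82, took 8.64% ± 4.95 of the counts in Ctrl, 8.44% ± 4.40 in KRAB and 4.50% ± 2.92 in NI at the 2-cell stage, against 0.337%, 0.235% and 0.360% in Ctrl, NI and VP64 at the 8-cell stage. Transcripts of the mitochondrial genome, a common measure of RNA quality, could not be read, because 0 of the 15 on the list were among the symbols. No label names separate cultures or animals for the libraries, so the p-values below measure the spread between these pools, which may be technical.

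The passage from the 2-cell to the 8-cell stage was compared first, within NI and within Ctrl, as the developmental background of the other comparisons. In NI embryos, genes of the egg and of the early 2-cell embryo fell and genes of protein synthesis rose. Oosp1, which encodes an oocyte-secreted protein (chromosome 19, 11667460 to 11691150 in GRCm38), fell from 1578 CPM (counts assigned to the gene divided by library size and scaled to a common total) to 4.01 CPM, a log2 fold change of -8.70 ± 0.87 (SE, n = 6 and 4). Zscan4c, a marker of the 2-cell embryo that guards telomeres in embryonic stem cells (chromosome 7, 11005745 to 11010547), was 988-fold lower at the 8-cell stage, with a counting interval of 273 to 8156, since few counts remained there. Fbp2, a fructose bisphosphatase, rose from 1.27 to 483 CPM (8.62 ± 0.97). Rpl3, a protein of the large ribosomal subunit (chromosome 15, 80077791 to 80091868), rose from 47.9 to 1480 CPM (4.94 ± 0.74).

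In NI, 6562 of 13158 genes tested by edgeR changed, 2433 upwards and 4129 downwards. In Ctrl 8092 changed, 2957 upwards and 5135 downwards. Both groups shared 1810 rising genes, against 547 expected of independent lists, and 3518 falling genes, against 1611 expected, while 20 genes passed in opposite directions. Across the 13158 genes, which are not independent replicates, the log2 fold changes of NI and Ctrl correlated with r = 0.83 (Spearman 0.82), and 95.1% of the genes called in NI had the same sign in Ctrl. The median of all tested genes was -0.47 in NI and -0.51 in Ctrl, and -0.72 and -0.70 with the size factors of DESeq2. With only the NI libraries in the fit, 5091 genes passed, 2494 upwards and 2597 downwards, and the median of all genes was 0.09. With only the Ctrl libraries 5877 passed, 2089 upwards and 3788 downwards, and the median was -0.44.

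Of the 68 maternal oocyte transcripts tested, messages laid down in the growing egg, 61 fell and 2 rose in NI, with a median log2 fold change of -5.06. Omt2a and Omt2b, expressed in oocytes, fell as well, with log2 fold changes of -8.27 ± 0.96 and -8.66 ± 0.99. In Ctrl 63 fell and 3 rose, with a median of -6.78, among them Wee2 (-9.83 ± 0.998), a kinase that holds the oocyte in meiotic arrest, and Oosp3 (-10.64 ± 1.12). Of the 42 genes of the 2-cell embryo and of zygotic genome activation, the first transcription of the embryo's own genome, 33 fell and 2 rose in NI, and 35 fell and 4 rose in Ctrl. Obox3, an oocyte homeobox gene of this list, fell in NI (-8.22 ± 1.03) and in Ctrl (-8.37 ± 1.04), and Zscan4f fell in Ctrl (-9.74 ± 1.08). The medians of this list were -5.10 in NI and -4.49 in Ctrl, and -5.01 and -4.49 with members at 0 counts in a group set to their bound. Camera called the maternal list (adjusted p = 2.35e-19 in NI and 1.21e-20 in Ctrl) and the 2-cell list (1.19e-09 and 2.08e-06). With an estimated correlation the maternal list had adjusted p = 0.0632 in NI and 0.111 in Ctrl, and the 2-cell list had adjusted p = 0.0632 and 0.133. Maternal counts were the same adjusted over the list alone, while 3 genes of the 2-cell list rose and 33 fell in NI, and 4 rose and 36 fell in Ctrl.

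All 78 cytosolic ribosomal protein genes rose in Ctrl and 49 rose in NI, with medians of 3.50 and 2.08 and with 0 falling in either group. Rpl7 rose in NI (4.27 ± 0.75) and in Ctrl (4.28 ± 0.59). Among 45 genes of ribosome biogenesis, 25 rose in NI and 30 in Ctrl, including Wdr12, a nucleolar factor for the large subunit (2.82 ± 0.65 and 2.86 ± 0.52). Of 53 nuclear genes of oxidative phosphorylation, 26 rose and 1 fell in NI, and 42 rose in Ctrl. Cyc1, cytochrome c1 of complex III, rose by 4.46 ± 0.67 in NI, and Uqcrb, another complex III subunit, by 5.07 ± 0.80 in Ctrl. Camera adjusted p-values in NI and Ctrl were 2.93e-16 and 2.53e-32 for the ribosomal proteins, 9.69e-07 and 1.38e-08 for ribosome biogenesis, and 5.37e-08 and 2.40e-12 for oxidative phosphorylation. With an estimated correlation they were adjusted p = 0.376 and 0.184, 0.319 and 0.233, and 0.319 and 0.184. With p adjusted over the list alone, 55 ribosomal protein genes, 26 of ribosome biogenesis and 27 of oxidative phosphorylation rose in NI, and 78, 30 and 42 in Ctrl.

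Markers of the first lineages moved both ways within their lists. Of 28 pluripotency and inner cell mass genes, 15 rose and 3 fell in NI, and 15 rose and 5 fell in Ctrl. Tdgf1, a Nodal co-receptor, rose in NI (7.60 ± 1.37), whereas Tcl1, an Akt co-activator that is also abundant in oocytes, fell (-7.44 ± 0.88). Of 25 trophectoderm genes, 13 rose and 3 fell in NI, with Aqp3, a water channel (6.17 ± 1.12), and Cdx2, the trophectoderm homeobox factor (4.90 ± 1.07), among the rising ones, and 11 rose and 6 fell in Ctrl. Camera called the pluripotency list (adjusted p = 0.00592 in NI and 0.00147 in Ctrl; adjusted p = 0.203 and 0.111 with an estimated correlation) and the trophectoderm list (adjusted p = 0.0175 and 0.0467; adjusted p = 0.319 and 0.479 with an estimated correlation). Of 48 DNA replication genes, 19 rose and 5 fell in NI, Tyms, thymidylate synthase, by 3.72 ± 0.71 (camera adjusted p = 0.000127, and adjusted p = 0.139 with an estimated correlation). The trophectoderm call in Ctrl was lost without Ctrl 2C replicate 2, 4 or 6 or Ctrl 8C replicate 1, 3 or 5 (adjusted p = 0.0532 to 0.0689). In Ctrl 9 DNA replication genes rose and 9 fell and the list was not called (adjusted p = 0.0691). By p adjusted over the list alone, 13 trophectoderm genes rose and 5 fell in NI, and 8 DNA replication genes rose and 9 fell in Ctrl, while the other counts of these lists were the same.

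Camera called none of the other lists between the stages, whereas fry and the exact permutation test of library means called some of them lower at the 8-cell stage. In Ctrl both called the lists of retrotransposon silencing (adjusted p = 0.00184 by fry and 0.0392 by exact permutation), chromatin (0.0191 and 0.0392), glycolysis (0.0236 and 0.0392) and interferon (0.00787 and 0.0412), and in NI that of interferon (0.000151 and 0.0125). Both also called the sperm markers in NI and Ctrl, and fry alone called the imprinted genes in NI (adjusted p = 0.00955). Neither test compares a list with the other genes, whose median lay at -0.47 in NI and -0.51 in Ctrl. Of 16 primitive endoderm genes 2 rose and 3 fell in each group, with Gata6, a transcription factor of that lineage, up by 4.90 ± 0.69 in NI. In NI the list's median was 0.90 and its mean -0.0015. Of 33 compaction, polarity and junction genes, 7 rose and 6 fell in NI and 6 rose and 11 fell in Ctrl. Cldn4, a tight junction claudin, rose in NI (7.24 ± 1.23), and Pard3, a polarity protein, fell in Ctrl (-6.04 ± 0.49). Of 63 genes of DNA and histone methylation, chromatin assembly and remodelling, 11 rose and 15 fell in NI and 12 rose and 23 fell in Ctrl, and Tet3, the 5-methylcytosine oxidase of the zygote, fell in both (-5.28 ± 0.54 and -6.46 ± 0.55). Of 40 genes of retrotransposon silencing and restriction, 8 rose and 12 fell in NI and 7 rose and 14 fell in Ctrl. Rnaseh2b, a subunit of ribonuclease H2, rose in NI (5.02 ± 0.70), and Piwil1, a PIWI protein that binds small RNAs, was at least 265-fold lower in Ctrl, where no counts remained at the 8-cell stage. Counts adjusted over the list alone were 11 rising and 13 falling chromatin genes in NI and 11 and 22 in Ctrl, 6 and 6 compaction genes in NI, and 1 and 3 primitive endoderm genes in Ctrl.

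Of 25 interferon and nucleic acid sensing genes, 2 rose and 8 fell in NI and 4 rose and 10 fell in Ctrl, with Ifitm3, an interferon-induced membrane protein, falling by 6.40 ± 0.85 in NI. Rising and falling members numbered 9 and 11 of 37 p53 targets, 7 and 6 of 43 stress and heat shock genes, 8 and 7 of 41 mitosis genes, and 5 and 6 of 21 glycolysis genes in NI. The same counts in Ctrl were 12 and 10, 9 and 15, 4 and 11, and 5 and 10. Those that differed when adjusted over the list alone were glycolysis in NI, with 5 and 7, and mitosis in Ctrl, with 3 and 11. Hspa8, a constitutive chaperone, rose in NI (4.82 ± 0.90) and Ldhb, lactate dehydrogenase B, fell in NI (-4.67 ± 0.64) and Ctrl (-6.45 ± 0.66). Of 20 imprinted genes 3 rose and 8 fell in NI and 4 rose and 6 fell in Ctrl, and of 18 genes of X chromosome activity 6 rose and 2 fell in NI and 6 rose and 5 fell in Ctrl. Markers of cumulus and granulosa cells, which surround the egg, fell for 7 and rose for 2 of 15 tested in NI, and fell for 6 and rose for 2 in Ctrl. Hsd3b1, a steroid dehydrogenase of that list, was at least 228-fold lower in NI. Of 6 sperm markers tested, 3 fell in NI and 4 in Ctrl, and their library means were lower at the 8-cell stage in both (exact permutation test, two-sided, adjusted p = 0.0125 in NI and 0.00306 in Ctrl).

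**Figure D1:**
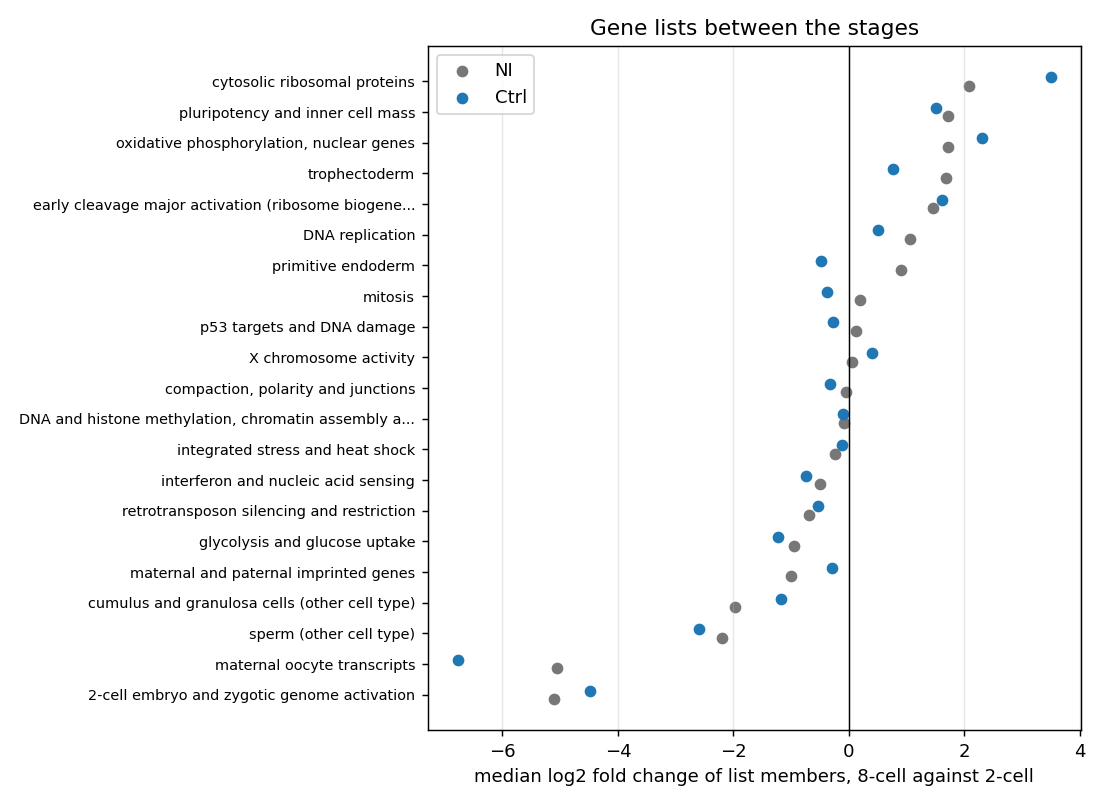
Median log2 fold change of the tested members of 21 gene lists (horizontal axis) between the 8-cell and the 2-cell stage, with 1 grey point for NI and 1 blue point for Ctrl per list. Ribosomal protein genes lie at 2.08 and 3.50, and maternal oocyte transcripts at -5.06 and -6.78.

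KRAB was compared with Ctrl at the 2-cell stage to ask which transcripts differed in embryos given the repressor. No single gene passed, and the genes with the smallest p-values were mostly lower in KRAB. Kat7, a histone acetyltransferase (chromosome 11, 95274259 to 95310246), stood at 31.2 ± 14.1 CPM in KRAB (SD, n = 6) against 131 ± 60.0 in Ctrl (n = 7), a log2 fold change of -2.07 ± 0.44 (SE), and was below the Ctrl median in 6 of 6 KRAB libraries. Mthfd1, a folate enzyme, differed by -2.03 ± 0.43, Elp2, an Elongator subunit, by -2.72 ± 0.59, and Elac2, which trims tRNA ends, by -2.81 ± 0.62. Tmem92, a transmembrane protein of the 2-cell list, was higher at 310 ± 156 against 85.9 ± 39.6 CPM (1.85 ± 0.42).

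The adjusted p of each of these 5 genes was 0.222, and edgeR called 0 of 11799 genes. At an unadjusted p under 0.05 there were 1838 genes (456 higher and 1382 lower, against 589.95 expected by chance). DESeq2 called 222 genes (49 higher and 173 lower) and limma-voom with quality weights 5252 (2569 higher and 2683 lower). Leaving out Ctrl 2C replicate 6 gave edgeR 159 genes (69 higher and 90 lower). In simulated data at these depths 32% of 4-fold and 82% of 8-fold changes were recovered in this comparison, among genes of 10 CPM or more drawn independently.

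As a group, ribosomal protein genes stood higher in KRAB, with a positive log2 fold change in 76 of 78 and a median of 0.998 (camera adjusted p = 1.32e-15, and adjusted p = 0.674 with an estimated correlation). The mean log2 CPM of these genes was 7.39 ± 1.03 (SD, n = 6) in KRAB and 6.01 ± 1.61 (n = 7) in Ctrl (exact permutation p = 0.0991). Of 68 maternal oocyte transcripts 12 had a positive value, and the median was -0.86 (adjusted p = 6.97e-05, and adjusted p = 0.674 with an estimated correlation), although the abundant members Omt2b (0.48 ± 0.70) and Dppa3 (0.36 ± 0.67), a maternal factor that protects the zygote's DNA methylation, had positive values. The 42 genes of the 2-cell embryo had a median of 0.46, with 29 positive (adjusted p = 0.000956, and adjusted p = 0.674 with an estimated correlation), including Sp110 (0.68 ± 0.40) and Gm4850 (1.56 ± 0.62). Genes of oxidative phosphorylation had a median of 0.67, with 40 of 53 positive (adjusted p = 0.000895), and those of ribosome biogenesis a median of 0.17, with 31 of 45 positive (adjusted p = 0.0175). Both had adjusted p = 0.674 with an estimated correlation. Cox8a, a subunit of cytochrome c oxidase, differed by 0.82 ± 0.59 and Npm1, nucleophosmin, by 0.36 ± 0.44. Fry called none of these 5 lists in 1 direction. When adjusted over the list alone, 4 maternal transcripts were lower and 1 gene each of the 2-cell and ribosome biogenesis lists was higher. The ribosome biogenesis call was lost without Ctrl 2C replicate 1, 5 or 7 or KRAB 2C replicate 1 or 3 (adjusted p = 0.102 to 0.163). Ribosomal proteins had a median of 1.61 without Ctrl 2C replicate 6. Ribosome biogenesis had a median of -0.013, 0.30 and 0.30 without KRAB 2C replicate 3, 4 and 2, and of 0.028, 0.051, 0.084, 0.29, 0.40 and 0.56 without Ctrl 2C replicate 7, 1, 5, 6, 4 and 2, respectively. Oxidative phosphorylation had a median of 0.38 without KRAB 2C replicate 5, and of 1.16 without Ctrl 2C replicate 6. Cumulus cell markers had a library mean of 2.74 ± 1.52 in KRAB and 2.02 ± 0.842 in Ctrl and were not called (adjusted p = 0.289), and the lists of retrotransposon silencing (median -0.35, 11 of 38 positive) and interferon (median 0.05, 13 of 23 positive) were not called either (adjusted p = 0.145 for both). Sperm markers were higher in KRAB by exact permutation before adjustment (p = 0.0239, adjusted p = 0.315).

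**Figure D2:**
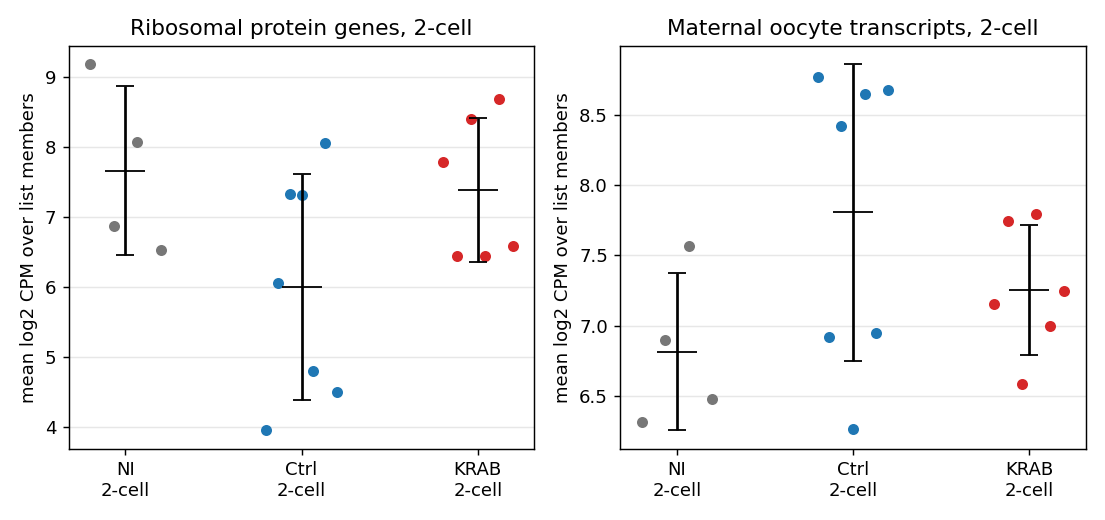
Mean log2 CPM over the members of the ribosomal protein list (left panel) and of the maternal oocyte list (right panel), with 1 point per 2-cell library of NI, Ctrl and KRAB, black dashes for group means and bars for SD. Ribosomal protein means were 7.67 in NI, 6.01 in Ctrl and 7.39 in KRAB, and the spread within Ctrl was 1.61.

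Ctrl was also compared with NI at the 2-cell stage, as the background against which the KRAB values stand. The smallest p-values belonged to genes with lower values in Ctrl. Sfrp2 and Sfrp4, secreted Wnt antagonists, stood at 0.0879 ± 0.121 and 0.0798 ± 0.211 CPM in Ctrl (SD, n = 7) against 16.9 ± 19.8 and 13.3 ± 11.9 CPM in NI (n = 4). Cox20, an assembly factor of cytochrome c oxidase (chromosome 1, 178319130 to 178322693), had a log2 fold change of -4.41 ± 0.81 (SE), and Chchd10, a mitochondrial protein, of -3.46 ± 0.70 (28.7 against 315 CPM). Both were below the NI median in 7 of 7 Ctrl libraries. Markers of cumulus and granulosa cells, another cell type that could be carried along, had a library mean of 2.02 ± 0.842 in Ctrl and 2.98 ± 1.08 in NI (exact permutation p = 0.130) and were not called (adjusted p = 0.215).

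None of these passed (adjusted p = 0.121 for each), and edgeR called 0 of 11799 genes, with 2756 at an unadjusted p under 0.05 (1743 higher and 1013 lower). DESeq2 called 1068 (680 higher and 388 lower) and limma-voom 5993 (3111 higher and 2882 lower), and without Ctrl 2C replicate 6 edgeR called 1374 (605 higher and 769 lower). Ribosomal protein genes had a median of -1.52, with 5 of 78 positive (camera adjusted p = 3.69e-15, and adjusted p = 0.716 with an estimated correlation), and Rplp2, a stalk protein of the ribosome, differed by -2.32 ± 0.73. Maternal transcripts had a median of 1.40, with 52 of 68 positive (adjusted p = 7.59e-07, and adjusted p = 0.716 with an estimated correlation), although Omt2a was at -0.86 ± 0.73. Oxidative phosphorylation genes had a median of -1.40, with 13 of 53 positive (adjusted p = 0.000369, and adjusted p = 0.716 with an estimated correlation), and Ndufa4, a respiratory chain subunit, differed by -2.41 ± 0.82. DNA replication genes had a median of 0.52, with 37 of 48 positive (adjusted p = 0.0114, and adjusted p = 0.633 with an estimated correlation), although the abundant members Gmnn, the licensing inhibitor geminin, and Orc6, of the origin recognition complex, were at -0.05 ± 0.47 and -0.29 ± 0.47. Fry called only DNA replication (adjusted p = 0.0328). By p adjusted over the list alone, 9 maternal, 5 DNA replication and 2 oxidative phosphorylation genes were higher and 2 oxidative phosphorylation genes lower. Without NI 2C replicate 1 the oxidative phosphorylation call was lost (adjusted p = 0.211), and without NI 2C replicate 3 the DNA replication call (adjusted p = 0.0884). DNA replication genes had a median of 0.24 and 0.32 without NI 2C replicate 3 and 1, and of 0.34 without Ctrl 2C replicate 2. Ribosomal proteins had a median of -0.59 without NI 2C replicate 1. Oxidative phosphorylation had a median of -2.19 without Ctrl 2C replicate 6, and of -0.35 without NI 2C replicate 1. The KRAB and NI comparisons with Ctrl use the same Ctrl libraries, so opposite signs in the 2 are partly built in.

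KRAB was also compared directly with NI at the 2-cell stage. Zbtb26, a zinc finger protein (chromosome 2, 37432168 to 37443135), stood at 3.43 ± 1.94 CPM in KRAB (SD, n = 6) and 19.08 ± 15.2 in NI (n = 4), and Tmem254a, a transmembrane protein, at 149 ± 44.2 and 42.5 ± 17.8 CPM. Nefl, the light neurofilament chain, differed by 3.49 ± 1.002 (SE) on the log2 scale and Zfp345, another zinc finger gene, by -2.07 ± 0.60. The adjusted p of these was 0.998. Of 11799 genes edgeR called 0, with 368 at an unadjusted p under 0.05 (137 higher and 231 lower), and DESeq2 and limma-voom called 0 each.

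Camera called 7 lists between KRAB and NI. The 2-cell embryo genes were higher in KRAB, with a median of 0.64 and 32 of 42 positive (adjusted p = 2.16e-05), as were maternal transcripts (0.31, 44 of 68, adjusted p = 0.00564), DNA replication genes (0.32, 31 of 48, adjusted p = 0.0332) and glycolysis genes (0.47, 16 of 20, adjusted p = 0.0332). For these 4 the adjusted p with an estimated correlation was 0.444, 0.869, 0.444 and 0.869. Ribosomal protein genes were lower (-0.57, 17 of 78, adjusted p = 0.0314), as were chromatin genes (-0.25, 21 of 62, adjusted p = 0.0332) and imprinted genes (-0.42, 6 of 17, adjusted p = 0.0434), with adjusted p = 0.869, 0.444 and 0.444 with an estimated correlation. Fry called 0 lists. Without NI 2C replicate 1 only 1 list was called and the ribosomal protein median turned to 0.37. Without KRAB 2C replicate 1, 2 or 6 or NI 2C replicate 3 the number was 3, 3, 2 and 3, and without KRAB 2C replicate 3 it was 8. The ribosomal protein call was lost without KRAB 2C replicate 2, 4 or 6 or NI 2C replicate 1 or 3 (adjusted p = 0.0660 to 0.540), and the maternal call without NI 2C replicate 1 or 4 (adjusted p = 0.0764 and 0.160). Chromatin was lost without KRAB 2C replicate 1, 2, 5 or 6 or NI 2C replicate 1, 3 or 4 (adjusted p = 0.0709 to 0.240), and imprinted genes without KRAB 2C replicate 1, 2, 4 or 6 or NI 2C replicate 1, 2 or 4 (adjusted p = 0.118 to 0.477). DNA replication was lost without KRAB 2C replicate 1, 5 or 6 or NI 2C replicate 1 or 3 (adjusted p = 0.0627 to 0.429), and glycolysis without KRAB 2C replicate 1, 2 or 6 or NI 2C replicate 1 or 3 (adjusted p = 0.126 to 0.475). The 2-cell list had a median of 0.36 without KRAB 2C replicate 1, and of 0.37 without NI 2C replicate 1. DNA replication genes had a median of 0.098 and 0.15 without NI 2C replicate 3 and 1, and of 0.18 without KRAB 2C replicate 1. Ribosomal proteins had a median of -0.88 and -0.38 without KRAB 2C replicate 5 and 4, and of -0.86 and 0.37 without NI 2C replicate 4 and 1, respectively. Glycolysis genes had a median of 0.11, 0.18 and 1.02 without NI 2C replicate 3, 1 and 2, and of 0.13 without KRAB 2C replicate 6. Imprinted genes had a median of -0.65 and -0.23 without KRAB 2C replicate 5 and 4, and of -0.24 and 0.033 without NI 2C replicate 1 and 4, respectively. Maternal transcripts had a median of 0.18 and 0.51 without NI 2C replicate 1 and 3, and of 0.19 without KRAB 2C replicate 2.

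VP64 was compared with Ctrl at the 8-cell stage to ask which transcripts differed in embryos given the activator. No single gene passed. Lrp2, the endocytic receptor megalin (chromosome 2, 69424340 to 69586065), stood at 3.74 ± 1.95 CPM in VP64 (SD, n = 7) and 14.8 ± 5.11 in Ctrl (n = 6), a log2 fold change of -1.98 ± 0.51 (SE). Xpo6, the exporter of actin, differed by -1.14 ± 0.30, and both were below the Ctrl median in 7 of 7 VP64 libraries. Ldha, lactate dehydrogenase A, was higher at 154 ± 97.3 against 44.9 ± 15.9 CPM (1.77 ± 0.46), Gdpd1, a phosphodiesterase of lysophospholipids, by 1.53 ± 0.40 and Uchl1, a ubiquitin hydrolase, by 1.34 ± 0.35.

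The adjusted p of these 5 genes was 0.999. Of 9850 genes edgeR called 0, with 393 at an unadjusted p under 0.05 (152 higher and 241 lower, against 492.5 expected by chance), DESeq2 called 1 and limma-voom 0. In simulated data 56% of 4-fold and 100% of 8-fold changes were recovered in this comparison, among genes of 10 CPM or more.

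Camera called 8 lists. Lower in VP64 were chromatin genes (median -0.31, 14 of 62 positive, adjusted p = 0.000193), trophectoderm genes (-0.53, 2 of 19, adjusted p = 0.00128), ribosome biogenesis genes (-0.20, 10 of 45, adjusted p = 0.00279), pluripotency genes (-0.36, 8 of 26, adjusted p = 0.00975) and compaction genes (-0.35, 8 of 30, adjusted p = 0.0187). With an estimated correlation none of these 5 passed, with adjusted p = 0.150, 0.267, 0.267, 0.0640 and 0.340 in that order. Higher were glycolysis genes (0.30, 12 of 20, adjusted p = 0.0131), p53 targets (0.16, 23 of 34, adjusted p = 0.0187) and 2-cell embryo genes (0.32, 20 of 29, adjusted p = 0.0187), and these had adjusted p = 0.436, 0.436 and 0.267 with an estimated correlation. The abundant chromatin genes Cbx3, heterochromatin protein 1 gamma, and Rbbp7, a histone chaperone, were at -1.10 ± 0.96 and -0.33 ± 0.49, and Obox6 and Sp110 of the 2-cell list were at -0.04 ± 0.40 and -0.77 ± 0.40. Retrotransposon silencing genes (median -0.20, 14 of 36 positive) and interferon genes (median -0.06, 7 of 15 positive) were not called (adjusted p = 0.705 and 0.916). Mean log2 CPM of the chromatin list was 5.19 ± 0.116 (SD, n = 7) in VP64 and 5.38 ± 0.119 (n = 6) in Ctrl (exact permutation p = 0.0111, adjusted p = 0.218). A single gene each of the 2-cell and glycolysis lists was higher and 1 trophectoderm gene lower when adjusted over the list alone. Fry called 0 of the 8. Without Ctrl 8C replicate 1 camera called 2 lists, and without Ctrl 8C replicate 5 or VP64 8C replicate 5 it called 5, and without Ctrl 8C replicate 6 it called 10. The 2-cell call was lost without Ctrl 8C replicate 1 or 5 or VP64 8C replicate 1, 2, 3, 4, 5 or 7 (adjusted p = 0.0510 to 0.424). The p53 call was lost without Ctrl 8C replicate 1, 3 or 4 or VP64 8C replicate 1, 4 or 5 (adjusted p = 0.0560 to 0.108), and the compaction call without Ctrl 8C replicate 1 or 5 or VP64 8C replicate 5 or 7 (adjusted p = 0.0510 to 0.150). Glycolysis was lost without Ctrl 8C replicate 1 or 6 (adjusted p = 0.0567 and 0.0612), pluripotency and trophectoderm without Ctrl 8C replicate 1 (adjusted p = 0.0510), and ribosome biogenesis without Ctrl 8C replicate 5 (adjusted p = 0.0605). The 2-cell list had a median of 0.12, 0.13, 0.13, 0.15 and 0.16 without VP64 8C replicate 3, 1, 2, 4 and 5, respectively. Compaction genes had a median of -0.21 and -0.19 without Ctrl 8C replicate 6 and 5, respectively. Ribosome biogenesis had a median of -0.13 without Ctrl 8C replicate 5. Glycolysis genes had a median of 0.14 and 0.16 without VP64 8C replicate 6 and 1, respectively. The p53 targets had a median of 0.10, 0.25 and 0.34 without VP64 8C replicate 1, 6 and 7, and of 0.27 and 0.39 without Ctrl 8C replicate 2 and 5, respectively. Cbx3 turned to 1.31 without Ctrl 8C replicate 6.

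VP64 was also compared with NI at the 8-cell stage, and again no single gene passed. Jarid2, a cofactor of the Polycomb complex PRC2 (chromosome 13, 44729474 to 44921643), stood at 51.97 ± 12.4 CPM in VP64 (SD, n = 7) and 161 ± 48.2 in NI (n = 6), a log2 fold change of -1.63 ± 0.29 (SE), below the NI median in 7 of 7. Ldha was at 154 ± 97.3 and 34.1 ± 22.7 CPM (2.18 ± 0.47), Slc25a31, a mitochondrial ADP/ATP carrier, at 2.30 ± 0.53, Xkr8, a phospholipid scramblase, at 1.88 ± 0.43 and Acer1, a ceramidase, at 1.88 ± 0.44. The adjusted p was 0.106 for Jarid2 and 0.254 for the other 4. Of 9850 genes edgeR called 0, with 706 at an unadjusted p under 0.05 (371 higher and 335 lower), DESeq2 called 22 (15 higher and 7 lower) and limma-voom 14 (11 higher and 3 lower). Without the 3 8-cell libraries that had the fewest detected genes, edgeR called 6 (4 higher and 2 lower).

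The 2-cell embryo genes were higher in VP64 than in NI, with 23 of 29 positive, a median of 0.21 and a mean of 0.95. Of the 42 members in the table these 29 passed the filter, which a gene can pass by its counts in 1 group. The rise was one among low values: 16 members high at the 2-cell and low at the 8-cell stage had a median of 225 CPM at the 2-cell stage. In NI at the 8-cell stage their median was 2.97 CPM. Gm2016, Gm5662 and Gm8300, near-identical copies of an Eif1a-like gene whose shared reads make the single values uncertain, were at 3.09 ± 0.62, 2.93 ± 0.68 and 2.41 ± 0.56, and Gm4850 at 2.48 ± 0.89. These 4 were chosen after their values were seen. The abundant member Obox6 was at -0.05 ± 0.40. The list's mean log2 CPM was 4.14 ± 0.428 (SD, n = 7) in VP64, 3.67 ± 0.170 (n = 6) in Ctrl and 3.14 ± 0.355 (n = 6) in NI. Camera called it (adjusted p = 2.84e-10), also with an estimated correlation (adjusted p = 0.00145) and by fry (adjusted p = 0.00158), while the exact permutation test of library means gave p = 0.00291 before and 0.0524 after adjustment. A total of 7 members were higher adjusted over the list alone. No single library left out ended the call. The 2-cell list had a median of 0.098, 0.13, 0.39, 0.43, 0.53 and 1.32 without NI 8C replicate 2, 1, 3, 5, 4 and 6, and of 0.13, 0.14 and 0.36 without VP64 8C replicate 2, 1 and 6, respectively.

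**Figure D3:**
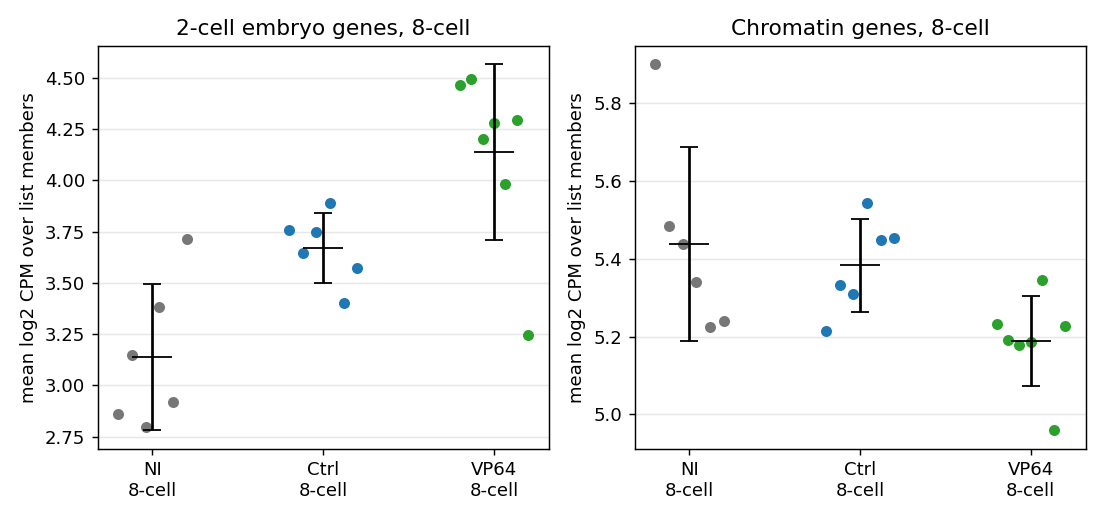
Mean log2 CPM over the members of the 2-cell embryo list (left panel) and of the chromatin list (right panel), with 1 point per 8-cell library of NI, Ctrl and VP64, black dashes for group means and bars for SD. The 2-cell list means were 3.14 in NI, 3.67 in Ctrl and 4.14 in VP64.

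A further 10 lists were called between VP64 and NI. Higher in VP64 were p53 targets (median 0.46, 28 of 34 positive, adjusted p = 2.45e-07), glycolysis genes (0.40, 16 of 20, adjusted p = 0.00263), stress and heat shock genes (0.25, 22 of 36, adjusted p = 0.0132) and maternal transcripts (0.18, 26 of 41, adjusted p = 0.0468). None of these 4 passed with an estimated correlation (adjusted p = 0.0702, 0.286, 0.345 and 0.368 in that order). Lower were trophectoderm genes (-0.72, 2 of 19, adjusted p = 4.81e-05), chromatin genes (-0.35, 14 of 62, adjusted p = 0.000167), compaction genes (-0.31, 7 of 30, adjusted p = 0.00263), pluripotency genes (-0.33, 8 of 26, adjusted p = 0.0107), ribosome biogenesis genes (-0.22, 12 of 45, adjusted p = 0.0168) and primitive endoderm genes (-0.72, 2 of 11, adjusted p = 0.0215). These 6 were lost too, at adjusted p = 0.0958, 0.0958, 0.154, 0.0511, 0.345 and 0.154 with an estimated correlation. The trophectoderm and primitive endoderm lists share the genes Dab2 and Fgfr2, so their values are not independent. Hdac1, a histone deacetylase of the chromatin list, was at -0.52 ± 0.35, and the abundant pluripotency genes Dppa5a and Fbxo15 were at 0.39 ± 0.55 and 0.02 ± 0.45. Fry called pluripotency (adjusted p = 0.0158) and chromatin (adjusted p = 0.0456) as well. Among trophectoderm genes 4 were lower, and 1 glycolysis gene was higher, adjusted over the list alone. The maternal call was lost without NI 8C replicate 1 or 3 or VP64 8C replicate 2, 4 or 7 (adjusted p = 0.0664 to 0.261), stress without NI 8C replicate 5 or 6 (adjusted p = 0.050003 and 0.0840), primitive endoderm without NI 8C replicate 4 or VP64 8C replicate 7 (adjusted p = 0.0620 and 0.0879) and ribosome biogenesis without NI 8C replicate 3 (adjusted p = 0.254). Chromatin genes had a median of -0.22 without NI 8C replicate 1. Ribosome biogenesis had a median of -0.11 without NI 8C replicate 3. Glycolysis genes had a median of 0.26 without NI 8C replicate 1. Stress genes had a median of 0.13, 0.14 and 0.39 without VP64 8C replicate 5, 1 and 7, and of 0.15 without NI 8C replicate 4. Maternal transcripts had a median of 0.10 without VP64 8C replicate 7, and of 0.27, 0.29 and 0.32 without NI 8C replicate 6, 5 and 4, respectively. Trophectoderm genes had a median of -0.44 without NI 8C replicate 6.

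Ctrl and NI were compared at the 8-cell stage as the background of the VP64 values. Afp, alpha-fetoprotein (chromosome 5, 90490737 to 90508907), stood at 15.2 ± 31.3 CPM in Ctrl (SD, n = 6) and 0.543 ± 0.400 in NI (n = 6), and Phlda2, an imprinted gene of the placenta, at 411 ± 807 and 54.2 ± 28.2 CPM. Dpep3, a membrane dipeptidase, differed by -1.17 ± 0.37 and Nup62cl by 1.72 ± 0.55. The adjusted p of these was 1, and Phlda2 turned to -0.10 without the 3 libraries of fewest detected genes. Of 9850 genes edgeR called 0, with 429 at an unadjusted p under 0.05 (315 higher and 114 lower), DESeq2 called 1 and limma-voom 0. The 2-cell embryo genes were higher in Ctrl, with a median of 0.28 and 18 of 29 positive (camera adjusted p = 5.07e-05, and adjusted p = 0.0328 with an estimated correlation), and 6 were higher adjusted over the list alone. Their library means differed by exact permutation before adjustment (p = 0.0130, adjusted p = 0.260). Obox6 and Sp110 were at -0.01 ± 0.42 and 0.95 ± 0.42. The p53 targets had a median of 0.33, with 27 of 34 positive (adjusted p = 0.00530, and adjusted p = 0.567 with an estimated correlation), and fry called neither list. The number of lists called was 4 without Ctrl 8C replicate 2, NI 8C replicate 5 or NI 8C replicate 6, and 1 without Ctrl 8C replicate 5, where the p53 call was lost (adjusted p = 0.0889). The 2-cell list had a median of 0.087 and 0.61 without NI 8C replicate 5 and 6, respectively. The p53 targets had a median of 0.20 without Ctrl 8C replicate 5.

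Whether Ctrl and NI differed by the same amount at both stages was tested as an interaction. Antxr2, an anthrax toxin receptor (chromosome 5, 97882783 to 98031043), had the smallest p, with a difference of log2 fold changes (8-cell minus 2-cell) of -6.96 ± 1.28 (adjusted p = 0.0522), followed by Nlrp4g (-7.40 ± 1.49) and Crip1 (4.92 ± 1.11; adjusted p = 0.0700 for both). Of 13158 genes edgeR called 0, with 2680 at an unadjusted p under 0.05 (892 higher and 1788 lower), DESeq2 called 693 and limma-voom 3600. Camera called ribosomal proteins (median 1.37, 72 of 78 positive, adjusted p = 7.62e-16), maternal transcripts (-1.74, 12 of 68, adjusted p = 1.80e-05), oxidative phosphorylation (1.23, 36 of 53, adjusted p = 0.00111) and DNA replication (-0.73, 9 of 48, adjusted p = 0.0157). All 4 had adjusted p = 0.655 with an estimated correlation, and fry called only DNA replication (adjusted p = 0.0455). Of single members adjusted over the list alone, 18 maternal, 3 DNA replication and 3 oxidative phosphorylation genes were lower.

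The position of each library between the stages was summarised as a stage score, the mean log2(CPM + 1) of the 200 genes that rose most minus that of the 200 that fell most in NI. The score was -3.83 ± 0.690 (SD, n = 6) in KRAB, -3.77 ± 1.20 (n = 7) in Ctrl and -3.89 ± 0.754 (n = 4) in NI at the 2-cell stage. It was 4.71 ± 0.228 (n = 7) in VP64, 5.01 ± 0.593 (n = 6) in Ctrl and 5.31 ± 0.162 (n = 6) in NI at the 8-cell stage, and the NI libraries, which defined it, differed by 9.20 between the stages. KRAB differed from Ctrl by -0.063 (exact permutation test, two-sided, p = 0.909) and VP64 from Ctrl by -0.299 (exact p = 0.248, adjusted p = 0.497). Without Ctrl 8C replicate 6 the VP64 difference was -0.517 (exact p = 0.00126), and with a pseudocount of 0.1 it was -0.637 (exact p = 0.0373).

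**Figure D4:**
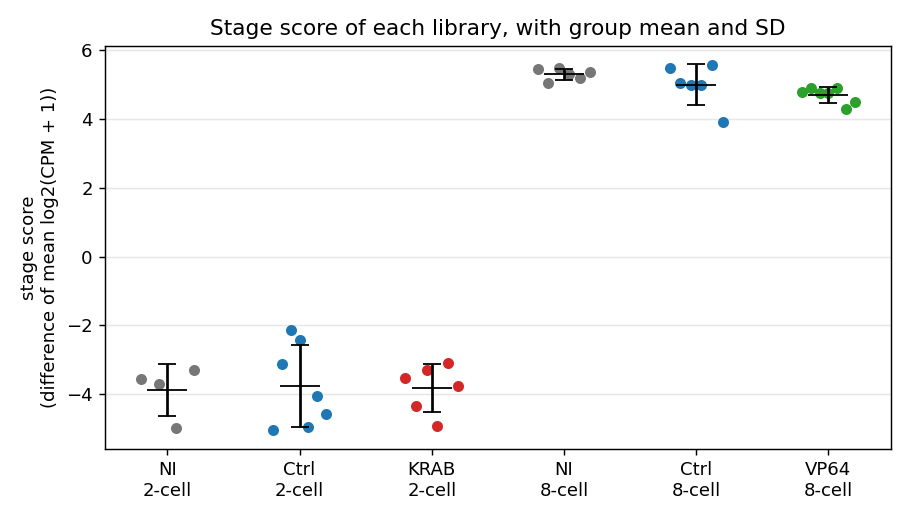
Stage score of each library (difference of mean log2(CPM + 1) between genes that rose and genes that fell from the 2-cell to the 8-cell stage in NI), with 1 point per library, black dashes for group means and bars for SD. The 2-cell groups lie near -3.83 and the 8-cell groups between 4.71 and 5.31.

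The KRAB change at the 2-cell stage and the VP64 change at the 8-cell stage, each against Ctrl of its own stage, were set against each other across 9093 genes. Their correlation was 0.035 (Spearman 0.035), with a jackknife SE of 0.340 over 26 libraries. Among genes at an unadjusted p under 0.05 in both, 13 were higher in both (5.17 expected of independent lists), 27 lower in both (21.4 expected), 2 higher in KRAB and lower in VP64 (8.49 expected) and 10 lower in KRAB and higher in VP64 (13.1 expected).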

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

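The test relating maternal and ribosomal protein means was chosen after the result was seen, as were the exact permutation test of lists, the removal of a length trend, the jackknife SE of the change that each correction made and the margin of 2 SE. Among 141 groups of values examined for a library far from the others, 12 were found, against 7.05 expected by chance.

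Ctrl 8C replicate 6 lay apart from the other Ctrl libraries in the stage score, at 3.92 (nearest other 4.99, median of the others 5.06). It also lay apart in the mean log2 CPM of the trophectoderm list, at 3.04 (4.22 and 4.53), of the primitive endoderm list, at 1.35 (2.66 and 3.04), and of the interferon list, at 4.26 (3.36 and 3.18). It had 9672 detected genes, the fewest of its group. VP64 8C replicate 7 lay apart in the 2-cell list, at 3.25 (3.98 and 4.29), in the stress and heat shock list, at 4.88 (5.92 and 6.002), and in the glycolysis list, at 3.64 (4.62 and 5.07). VP64 8C replicate 6 lay apart in the chromatin list, at 4.96 (5.18 and 5.21). NI 8C replicate 5 lay apart in the trophectoderm list, at 3.31 (4.43 and 4.75), and in the compaction list, at 3.78 (4.52 and 4.62). NI 2C replicate 3 lay apart in the ribosome biogenesis list, at 5.52 (6.60 and 6.67), and in the cumulus and granulosa list, at 1.37 (3.38 and 3.40).

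The difference between Ctrl and NI changed between the stages for 4 lists by camera on the interaction term, with medians of 1.37 for ribosomal proteins, -1.74 for maternal transcripts, -0.73 for DNA replication and 1.23 for oxidative phosphorylation. With an estimated correlation adjusted p = 0.655 for each of the 4.

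Ribosomal protein genes were lower, and maternal transcripts higher, in the 2-cell Ctrl libraries than in KRAB, with medians of 0.998 and -0.86 for KRAB against Ctrl, but both lists had adjusted p = 0.674 with an estimated correlation, and their library means differed by 1.39 ± 0.739 (SE; exact permutation p = 0.0991) and by -0.554 (exact p = 0.256). With all libraries thinned to 1043740 counts the ribosomal protein median was 0.947, a change of -0.051 ± 0.108 (jackknife SE over libraries). Random thinning keeps each gene's expected share of its library. It could hardly move genes counted this often, so it does not decide whether depth contributed to the ribosomal difference. Length bias cannot be told apart, because removal of a trend on transcript length left a median of 0.759, a change of -0.239 ± 0.218, above the bound of 0.5 by less than 2 SE. The ribosomal protein mean also followed each library's slope on length (r = -0.683, Spearman -0.650, permutation p = 0.00181 and 0.00597, adjusted p = 0.00724 and 0.0152 over 4 relations, r = -0.528 without the 2 farthest libraries). Removal of a trend on GC content left a median of 0.909, a change of -0.089 ± 0.205, which alone leaves GC bias open by the same margin. The library means then still differed by 1.39, a change of -0.012 ± 0.087 (SE). With the length trend removed they differed by 1.07, a change of -0.336 ± 0.149. On this measure neither trend accounts for the whole difference. The bound, however, was set on the median, by which both stay open. Leaving out the 10 most counted genes left a median of 0.999, a change of 0.001 ± 0.003 (jackknife SE), and moved other genes by a median of only 0.0015. Under TMM scaling this removal could hardly move any gene, so it does not decide whether counts taken by these 10 genes contributed. Pools at different points of maternal transcript clearance may also account for the ribosomal difference, since the means of both lists correlated within groups over 17 libraries (r = -0.640, Spearman -0.632, permutation p = 0.00611 and 0.00758, adjusted p = 0.0122 and 0.0152, r = -0.527 without the 2 farthest). A correlation within groups does not show that the groups differed in clearance. The stage scores of KRAB and Ctrl differed by -0.063 (exact permutation p = 0.909), within their spread. The ribosomal protein mean of the NI libraries, at 7.67 ± 1.21 (SD), lay nearer to KRAB (7.39 ± 1.03) than to Ctrl (6.01 ± 1.61). By exact permutation p was 0.681 for KRAB against NI and 0.109 for Ctrl against NI. An effect of KRAB itself stays open and untested.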

How the results depend on the processing

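Removing the length trend, leaving out the 3 8-cell libraries with the fewest detected genes or Ccdc82, and the exact permutation of list means were chosen after the data were seen. Counts of genes stayed within 1.5 times in 196 of 211 settings over 9 comparisons, and counts of lists in 100 of 136. In the 6 comparisons within a stage and the interaction the main count of genes was 0, so a kept count there means 0 genes again. Of 6166 settings for 266 single genes 6000 kept direction and side of the threshold, 39 lost the call, 76 gained one and 51 turned. Of 829 settings for 56 lists 658 kept their call, 170 lost it and 1 turned. No gene or list named between the stages turned. No paired analysis was possible because replicate numbers only name libraries. No 2-cell library was under the depth limit, so leaving out low-depth libraries gave no value within that stage, and the pseudocount alternative for normalized values was not run, since the table holds counts. Small changes would mostly be missed: at a 2-fold change 2% of simulated genes of 10 CPM or more were recovered for KRAB against Ctrl. Depth was not separated from the spread between libraries. The cause of the changes below was not tested.

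Where edgeR called 0 genes, DESeq2 called 222 and limma-voom 5252 for KRAB against Ctrl, 1068 and 5993 for Ctrl against NI at the 2-cell stage, and 22 and 14 for VP64 against NI. DESeq2 called 1 for VP64 against Ctrl and 1 for Ctrl against NI at the 8-cell stage. Without the 3 8-cell libraries VP64 against NI gave 6. The interaction gave 693 by DESeq2, 3600 by limma-voom, 2 with no filter and 1 without low-depth libraries. Leaving out single libraries gave 0 to 159 genes for KRAB against Ctrl and 0 to 1374 for Ctrl against NI at the 2-cell stage, both highest without Ctrl 2C replicate 6.

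With an estimated correlation, 0 lists were called for KRAB against Ctrl, Ctrl against NI at the 2-cell stage, KRAB against NI, VP64 against Ctrl, the interaction and both comparisons between stages, 1 for Ctrl against NI at the 8-cell stage and 1 for VP64 against NI. Fry called 0 for KRAB against Ctrl, KRAB against NI, VP64 against Ctrl and Ctrl against NI at the 8-cell stage, 1 for Ctrl against NI at the 2-cell stage, 1 for the interaction, 3 for VP64 against NI and 12 between stages in Ctrl. Exact permutation called 0 in each of the 6 within-stage comparisons and 11 between stages in Ctrl. Single libraries left out gave 1 to 4 lists for Ctrl against NI at the 8-cell stage, 2 to 10 for VP64 against Ctrl and 1 to 8 for KRAB against NI, where the ribosomal protein median ran from -0.88 (without KRAB 2C replicate 5) to 0.37 (without NI 2C replicate 1).

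By limma-voom Scarna13 was at 0.022 for KRAB against NI, Obox6 at 0.14 for Ctrl against NI at the 8-cell stage, and Fbxo15 at -0.15 and Cbx3 at -0.35 for VP64 against NI. With the length trend removed Gmnn was at 0.061 for Ctrl against NI at the 2-cell stage, Obox6 at 0.028 for Ctrl against NI at the 8-cell stage and Fbxo15 at -0.061 for VP64 against NI. With the title number Obox6 was at 0.019 for Ctrl against NI and Fbxo15 at -0.082 for VP64 against NI, and with no filter Fbxo15 was at -0.015. For VP64 against Ctrl, Obox6 was at 0.012 with only the groups compared and 0.013 at 10 CPM, and Cbx3 at 0.51 with detected genes as covariate. Without the 3 8-cell libraries Phlda2 was at -0.10 and Obox6 at 0.15 for Ctrl against NI, and Dppa5a at -0.23 and Cbx3 at -0.89 for VP64 against NI. Without single libraries Ctrl against NI at the 2-cell stage ran from -1.46 (without Ctrl 2C replicate 6) to 0.29 (without NI 2C replicate 3) for Omt2b and from -0.51 to 0.073 for Gmnn. VP64 against Ctrl ran from -0.41 to 0.13 for Obox6 and from -2.44 (without VP64 8C replicate 7) to 1.31 (without Ctrl 8C replicate 6) for Cbx3. Obox6 ran from -0.15 to 0.19 for Ctrl against NI at the 8-cell stage. VP64 against NI ran from -0.43 to 0.091 for Obox6, -0.22 to 0.71 for Dppa5a, -0.20 to 0.27 for Fbxo15 and -0.89 to 0.94 for Cbx3.

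The stage score difference of KRAB was 0.150 with 1000 axis genes each way, and ran from -0.278 (without Ctrl 2C replicate 1) to 0.208 (without Ctrl 2C replicate 3), turning also without Ctrl 2C replicate 2 (0.042) or 4 (0.159) or KRAB 2C replicate 2 (0.039) or 4 (0.158). That of VP64 was -0.637 with a pseudocount of 0.1 (exact p = 0.0373) and -0.540 without the 3 8-cell libraries (exact p = 0.00476), and ran from -0.517 (without Ctrl 8C replicate 6, exact p = 0.00126) to -0.186 (without Ctrl 8C replicate 5).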

Other observations

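The exact permutation test of list means, the fit with detected genes, the matching for carry-over and the members with little shared sequence were chosen after the data were seen.

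Among chromatin regulators that passed between the stages, the paralogs Tet2 and Tet3, which oxidise 5-methylcytosine, went opposite ways in NI, with Tet2 at 3.55 ± 0.77 (log2 fold change ± SE, n = 6 and 4) and Tet3 at -5.28 ± 0.54. Kdm1b, a histone demethylase of the oocyte, fell (-3.64 ± 0.67), and Uhrf1, which guides maintenance methylation, fell in Ctrl (-4.98 ± 0.61). Other single genes that fell in NI were Egr1, an immediate early gene (-6.07 ± 0.99), Irf1, an interferon regulator (-5.53 ± 0.87), and Gadd45a, a growth arrest gene (-5.12 ± 0.90), while the stress and heat shock list as a whole was not called by camera (adjusted p = 0.566). Perp, a p53 target of desmosomes, rose (5.38 ± 0.96), and so did the claudin Cldn7 (5.63 ± 0.92). Among imprinted genes Snrpn was at least 146-fold lower at the 8-cell stage in NI and at least 153-fold lower in Ctrl, where no counts remained.

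The 2-cell list was higher in VP64 than in NI at the 8-cell stage, with library means of 4.14 and 3.14 on the log2 scale, while Ctrl at 3.67 already lay 0.532 above NI (camera adjusted p = 5.07e-05, and adjusted p = 0.0328 with an estimated correlation) and VP64 against Ctrl had adjusted p = 0.267 with an estimated correlation. Summing near-identical copies merged only 4 tested members into 1 and left 0.851 (exact permutation p = 0.0035), and 18 members that share less than 5% of 31-base words with another member differed by 0.635 ± 0.167 (exact p = 0.00233). This argues against reads shared among members of the list as the whole cause but not as a part of it. Sequence shared with genes outside the list was not measured for these members. Carry-over of 2-cell RNA or reads would raise a gene by its ratio of 2-cell to 8-cell level, yet library means of 131 other genes, matched to all 29 tested members on that ratio with the 8-cell level taken from Ctrl, differed by 0.164 ± 0.0904 (SE), 0.837 ± 0.154 less than those of the list (exact p = 0.00175), which argues against it as the whole cause. Libraries with few detected genes could raise the list only if VP64 and NI differed in that number. They differed by only 160.5 detected genes (exact permutation p = 0.805). With this number as a linear covariate over all 19 libraries, the difference of the list was still 0.986 ± 0.185 (SE). A gap this small left the fit little room to move the difference, so the fit itself decides nothing. Numbers this close argue against detected genes as the whole cause, as far as their relation to the list is linear. An earlier position of the VP64 pools between the stages cannot be told apart, because a score from the Ctrl libraries differed by -0.026 (exact p = 0.932), within its spread, and an effect of the activator may also account for the part above Ctrl and stays an untested hypothesis.

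Ccdc82 was the most counted gene of most 2-cell libraries. It shared 13.996% of its 31-base words with transcripts of other genes, against a median of 11.2% over 95 highly counted genes, so reads from other genes may add to its count and cannot be told apart from its own. No biological explanation was tested.

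Other splits of the same libraries tell whether chance can be excluded. Genes at an unadjusted p under 0.05 were as many in 14 of 100 splits for KRAB against Ctrl (real 1838, highest other 5957), 8 of 100 for Ctrl against NI at the 2-cell stage (2756 and 3834) and 40 of 100 for KRAB against NI (368 and 1643). At the 8-cell stage they were as many in 44 of 100 for VP64 against Ctrl (393 and 2472), 74 of 100 for Ctrl against NI (429 and 2380) and 22 of 100 for VP64 against NI (706 and 2475), and for the interaction in 4 of 50 (2680 and 3166). Chance cannot be excluded for any of these 7 counts. Some splits gave several times the real count, and the source of such high counts was not tested. The same holds for the counts of other tools: 17 of 100 splits gave as many genes by limma-voom for KRAB against Ctrl (5252 and 7052) and 20 of 100 for Ctrl against NI at the 2-cell stage (5993 and 7685), and by DESeq2 2 of 30 (222 and 1000) and 3 of 30 (1068 and 2197). For the 2 comparisons between the stages chance was excluded, as 1 of 50 splits, the real one, gave as many genes in NI (6562 and 3775) and 1 of 50 in Ctrl (8092 and 902). Numbers of lists called by camera with a preset correlation were as large in 49 of 100 splits for KRAB against Ctrl (5 and 8), 49 of 100 for Ctrl against NI at the 2-cell stage (4 and 7), 13 of 100 for KRAB against NI (7 and 9) and 81 of 100 for Ctrl against NI at the 8-cell stage (2 and 9), so that chance cannot be excluded. Below a share of 0.05, with no adjustment for the 6 comparisons, were VP64 against Ctrl, with 3 of 100 (8 and 8), where 2 other splits called as many lists as the real one, and VP64 against NI, with 1 of 100 (11 and 10). Chance is excluded only in that sense: with an estimated correlation 0 and 1 of these lists were called, by exact permutation 0 and 0, and for VP64 against Ctrl camera called 2 without Ctrl 8C replicate 1 and 5 without Ctrl 8C replicate 5 or VP64 8C replicate 5.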
